A study of Mus musculus with 3 samples.

How the data were processed

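Single-cell RNA sequencing was measured in 3 libraries from B16F10 tumours, a mouse melanoma line grown under the skin. Each library pooled the tumours of 6 mice, so the groups saline, vaccine and combination held 1 library each and there were no replicates. Per the series description, mice received 2 injections, on days 2 and 8, and tumours were collected on day 10. The vaccine was 50 µg of the M44 peptide with 20 µg of CpG, a DNA oligonucleotide that activates Toll-like receptor 9. In the combination group a TIGIT antibody was added to it; the dose and clone of the antibody are not given in the sources used here. Per the labels' protocols, tumours were digested with enzymes, strained and enriched for CD45-positive leukocytes with magnetic beads, and libraries were made with the 10x 3′ v2 kit.

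The deposited matrices hold UMI counts per gene and cell barcode, that is, count values without normalisation, made by the authors with Cell Ranger 5.0.1 per the file headers. The genome was GRCm38 per the submitters' processing notes, and the files list 32285 genes with Ensembl IDs, of which 78 symbols are used more than once. Seurat 4.1.1 is named in the processing notes without a stated role, and the filters that chose the barcodes are not given in the sources used here. All values were checked to be whole numbers, and the lowest total of any listed barcode was 500 UMIs in each library, so cells with less RNA are absent. Other files of the deposit hold barcodes and gene names only.

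Barcodes with under 200 genes or over 15% mitochondrial UMIs were removed. Doublets were scored with Scrublet as built into scanpy 1.11.5, within each library. The automatic score threshold, planned before the data were examined, marked 0 barcodes of the saline library against 639 of the vaccine and 996 of the combination library. The highest-scoring barcodes were therefore removed at the same relative rate in each library, 50 percent of the expected rate of 0.8% per 1000 barcodes, which gave 5.91%, 6.46% and 6.27%. This change was made after seeing the scores, and the automatic threshold was kept as an alternative.

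Kept cells were scaled to 10000 UMIs and log-transformed, and genes seen in under 10 cells were left out. The 2000 most variable genes, 30 principal components and 15 neighbours gave a shared-nearest-neighbour graph, clustered with Leiden at resolution 1 and seed 0 without integration of the libraries. This used anndata 0.12.19, igraph 0.11.9, leidenalg 0.10.2, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 under Python 3.11.15, and plots used matplotlib 3.10.9. Clusters were named from marker lists fixed before the data were examined, when at least 3 markers of a type were at least 2-fold above the other clusters and present in at least 10% of the cells. T and NK clusters were clustered again. Sub-clusters were called CD8 at a CD8 to CD4 ratio of at least 16 and CD4 at a ratio of at most 0.25, thresholds set after seeing the ratios. In all, 25 clusters and 13 T and NK sub-clusters resulted, of which 2 clusters and 2 sub-clusters were left unnamed. Names end in "-like" because they rest on RNA alone.

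The unnamed groups were kept in the total. A T-lineage sub-cluster with few UMIs, left out of T-like cells by a threshold set after seeing it, made up 10.3%, 10.4% and 11.9% of saline, vaccine and combination cells. A sub-cluster led by macrophage genes made up 2.32%, 1.87% and 2.04% in the same order. A cluster with few UMIs (median 893.5) made up 4.33%, 4.78% and 5.22%. Its markers were nearest to macrophages, but none was among its leading genes, and it was left out of macrophage-like cells. The last unnamed cluster held 62 saline cells, 0 vaccine cells and 1 combination cell. T-like cells whose subset was not resolved, among them the cycling and the interferon-responding sub-clusters, were 3.62%, 2.60% and 2.49% of cells and were counted in T-like cells as a whole.

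Shares of cells are given with exact Clopper-Pearson 95% intervals, and ratios of shares with exact conditional intervals. For expression, UMIs were summed over the cells of a class in each library and scaled by the class total to CPM, with exact Poisson 95% intervals. Ratios of CPM on the log2 scale have exact conditional binomial intervals. All these intervals cover counting error only, not differences between mice or libraries. No test was made and no p-value is given, since cells are not replicates; for the same reason no count of changed genes over the transcriptome is given. "Higher" and "lower" below describe these libraries alone.

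The genes named below follow a rule fixed before the data were examined. In each of the 4 classes with the most cells (macrophage-like, CD8 T-like, CD4 T-like and monocyte-like) and each of the 3 comparisons, it takes the 3 genes with the highest and the 3 with the lowest CPM ratio. Eligible genes had at least 100 UMIs over both libraries, at least 20 CPM in the higher one, a ratio of at least 1.5 in either direction and an interval that excluded equal values. Markers of other classes, gene models without a name, mitochondrial, ribosomal, haemoglobin, immunoglobulin, T cell receptor and sex-linked genes were left out. The rule also takes up to 2 members with the highest and 2 with the lowest ratio of each gene list, and Tigit, Cd226, Pvr, Nectin2, Pdcd1, Cd274, Ifng, Gzmb and Foxp3 in every case. Positions come from GENCODE vM21 on GRCm38, matched by Ensembl ID for 53 of 53 named genes.

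In addition, 23 gene lists were fixed before the data were examined. For T-like and NK-like cells they were cytotoxic effector, checkpoint receptors and exhaustion, naive and memory T cell, Th1 and T cell help, regulatory T cell program and T cell costimulation. For macrophage-like, monocyte-like or dendritic-like cells they were interferon gamma response, MHC class II presentation, inflammatory macrophage, alternative macrophage, tumour macrophage lipid and tissue program, dendritic cell maturation, leukocyte attracting chemokines, checkpoint ligands and Toll-like receptor and NF-kB. Both sets used cell cycle, type I interferon response, MHC class I presentation, hypoxia and glycolysis and TIGIT axis. In every class, dissociation stress, free RNA from tumour cells and mitochondrial transcripts were measured. Of the listed genes, 382 entries are in the files and 3 are not. A member counts as measured with at least 50 UMIs in a class over both libraries. Each list has the median log2 ratio of its measured members, with 0.5 added to each count, an interval from Poisson draws, the number of members at least 1.5-fold higher or lower, and the percentile of its median among 10000 random lists matched on mean expression. Lists overlap: inflammatory macrophage and interferon gamma response share 3 genes, and regulatory T cell program and T cell costimulation share 4.

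For shares of cells with a UMI of a gene, each cell was thinned to 1000 UMIs and shallower cells were left out. Macrophage-like cells served as background for T cell genes, since RNA set free from broken cells gives UMIs in cells that do not express a gene. The background of macrophage RNA in CD8 T-like, CD4 T-like, monocyte-like and neutrophil-like cells was estimated from C1qa, C1qb and C1qc.

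On data simulated from these libraries with Poisson counts, the rule for named genes was tested in the 4 classes. Simulated 2-fold and 4-fold differences passed in 94% to 100% of 50 genes per class and comparison, 1.5-fold differences in 34% to 54%, and unchanged genes in at most 0.593%. All simulated 2-fold lists were recovered, at a percentile of 100.

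Alternatives planned before the data were examined were a mitochondrial limit of 8%, at least 500 genes, doublets kept, resolutions of 2 and 0.5, each library clustered alone, immune-named cells as the total, size factors (median of ratios), each cell scaled equally, list members with at least 10 or 200 UMIs, and thinning to 500 or 2000 UMIs or none. Added after seeing the data were the automatic doublet threshold, cells with at least 2000 UMIs only, the low-UMI sub-cluster counted as T-like, macrophage-like and monocyte-like cells together ("phagocyte-like"), all T-like cells together for the T cell lists, stress and Toll-like receptor lists in further classes, and macrophage-like cells without clusters that hold under 1% of a library's macrophage-like cells or from the largest saline cluster alone. Scaling by size factors instead of totals moved the log2 median of all genes by over 0.1 in 5 small classes only. The shifts for vaccine over saline were −0.31 in neutrophil-like, −0.21 in regulatory T-like, −0.17 in gamma-delta T-like and −0.17 in plasmacytoid dendritic-like cells. For combination over vaccine they were 0.32 in neutrophil-like, −0.21 in B-like and 0.12 in plasmacytoid dendritic-like cells. For combination over saline they were −0.24 in B-like, −0.21 in regulatory T-like and −0.11 in gamma-delta T-like cells.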

Results

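Leukocytes of B16F10 tumours were profiled by single-cell RNA sequencing in 3 groups of mice. B16F10 is a mouse melanoma line that forms tumours under the skin and is used as a model of poorly inflamed tumours. The saline group received injections without vaccine. The vaccine group received the M44 peptide, described by the series title as a neoantigen presented on MHC class II, with CpG as adjuvant. The combination group received the same vaccine and an antibody to TIGIT, an inhibitory receptor of T and NK cells that binds Pvr (CD155) and Nectin2 (CD112). Each group gave 1 library from the pooled tumours of 6 mice, without replicates, so every difference below compares single libraries.

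The libraries held 14776 barcodes with saline, 16161 with the vaccine and 15684 with the combination, and 83910402, 74276333 and 75912203 UMIs in the same order. The median barcode had 3538, 3185 and 3305 UMIs and 1398, 1328 and 1370 genes. After filters for genes, mitochondrial share and doublets, 13523, 14758 and 13857 cells remained. Shares below are of these kept cells, which had passed the CD45 bead sort and the 500 UMI minimum of the files, and so they are not shares of the whole tumour. The mitochondrial limit removed 2.71% [95% interval 2.46–2.99] of saline, 2.33% [2.11–2.58] of vaccine and 5.73% [5.37–6.11] of combination barcodes.

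T-like cells made up a lower share with the vaccine and a still lower share with the combination, while macrophage-like and monocyte-like cells made up more. T-like cells were 39.8% [39.0–40.6] of cells with saline, 29.1% [28.4–29.9] with the vaccine and 20.3% [19.6–21.0] with the combination. Cells of the phagocyte lineages, macrophage-like or monocyte-like, were 32.4% [31.7–33.2], 43.9% [43.1–44.8] and 51.0% [50.1–51.8]. CD8 T-like cells, the cytotoxic subset, were 20.9% [20.3–21.6], 16.5% [15.9–17.1] and 10.8% [10.3–11.4], and CD4 T-like helper cells were 14.7% [14.1–15.3], 9.78% [9.30–10.3] and 6.69% [6.28–7.12]. The T-like share with the vaccine was 0.732 [0.703–0.762] times that with saline, and the share with the combination was 0.696 [0.663–0.730] times that with the vaccine. Regulatory T-like cells, which restrain other T cells, were few, with 25, 17 and 18 cells. The order of the T-like shares between combination and vaccine turned when each library was clustered alone, to a ratio of 1.252. The CD4 T-like ratios then turned to 1.58 for vaccine over saline and 1.12 for combination over saline. Counted over all barcodes without filters or clusters, 46.5% of saline, 35.2% of vaccine and 27.7% of combination barcodes had more T cell than macrophage marker UMIs. This count keeps the order of the joint clustering.

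**Figure D1:**
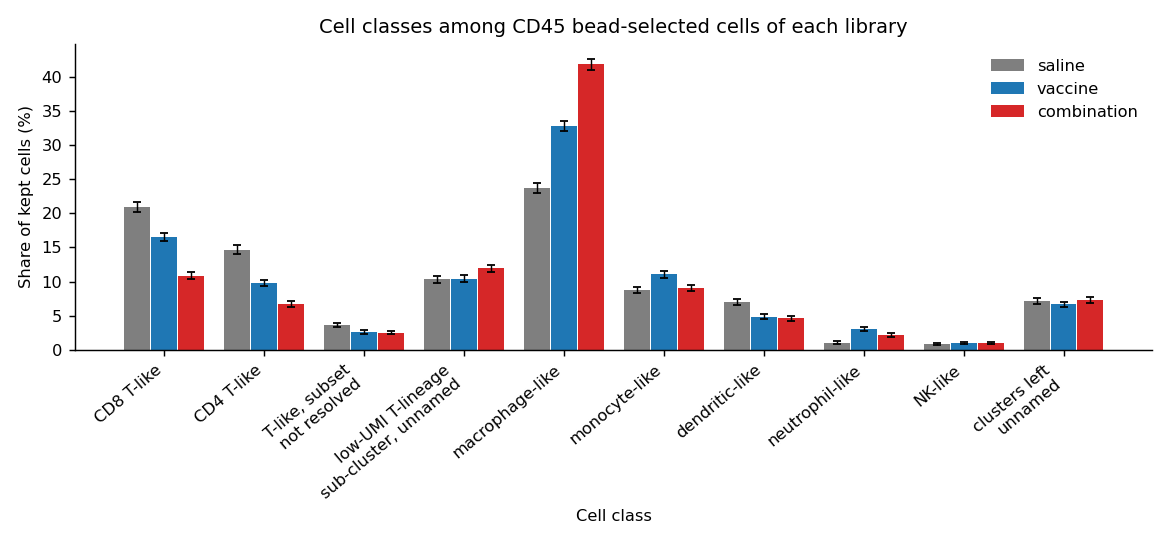
Share of kept cells (%, y axis) in each cell class (x axis) for the saline, vaccine and combination library; error bars are exact 95% intervals for counting error. CD8 T-like cells go from 20.9% with saline to 10.8% with the combination, and macrophage-like cells from 23.7% to 41.9%.

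Among phagocytes, macrophage-like cells were 23.7% [23.01–24.4], 32.9% [32.1–33.6] and 41.9% [41.1–42.7], and monocyte-like cells 8.72%, 11.1% and 9.06%. The boundary between these classes moved with the processing, and with doublets kept the monocyte-like ratio of vaccine over saline was 0.581 instead of 1.27. Neutrophil-like cells were 1.04% [0.878–1.23] with saline, 3.05% [2.78–3.34] with the vaccine and 2.13% [1.90–2.38] with the combination. Dendritic-like cells, which present antigen to T cells, were 6.92%, 4.86% and 4.61%. Within them, migratory dendritic-like cells, the mature form that carries antigen to lymph nodes, were 1.501% [1.30–1.72], 0.725% [0.595–0.875] and 0.657%. NK-like cells were 0.806% [0.662–0.972], 0.983% [0.830–1.16] and 1.01% [0.851–1.19]. B-like cells were 59 of the saline, 10 of the vaccine and 12 of the combination cells.

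The first comparison, vaccine over saline, asks how the leukocytes of the tumour differ after the peptide vaccine with its adjuvant. Macrophage-like cells of the vaccine library had median log2 ratios below 0 for the alternative macrophage list and the lipid and tissue program, and above 0 for the inflammatory and interferon gamma response lists. Saa3, an acute-phase protein made by activated macrophages, was at 3317 CPM [3296–3338] with the vaccine and 53.3 CPM [50.8–55.9] with saline, a 62.2-fold difference. Retnla, a secreted marker of alternative activation, was at 6.89 CPM [5.97–7.92] with the vaccine and 155.8 CPM [151.5–160.2] with saline. In CD8 T-like cells 8 of 13 measured Toll-like receptor and NF-kB genes were higher, and the inhibitory receptor gene Ctla4 was at 107.6 CPM in vaccine and 33.6 CPM in saline CD8 T-like cells.

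The fixed rule also named Lcn2, Lipg, Cd209f and Cd209g in macrophage-like cells. Lcn2, an iron-siderophore binding protein of inflammation, was at 34.2 CPM [32.1–36.3] with the vaccine and 1.14 CPM [0.802–1.57] with saline. It also leads the neutrophil-like cluster, at 10730 CPM in vaccine neutrophil-like cells. These were 3.05% of vaccine and 1.04% of saline cells. Free neutrophil RNA was not estimated, so the Lcn2 difference was not shown to belong to macrophage-like cells. Lipg, an endothelial-type lipase, was at 50.4 CPM and 4.34 CPM. The C-type lectins Cd209f and Cd209g, found on resident macrophages, were at 1.34 CPM [0.956–1.84] and 0.655 CPM with the vaccine, against 51.1 CPM [48.6–53.6] and 21.4 CPM with saline. Saa3 lies on chromosome 7 at 46711998–46715700 on the minus strand (ENSMUSG00000040026), Cd209f on chromosome 8 at 4102787–4105835 on the minus strand (ENSMUSG00000051906) and Retnla on chromosome 16 at 48842551–48844461 on the plus strand (ENSMUSG00000061100). All are protein-coding genes in the GRCm38 annotation.

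These genes also mark clusters that were unevenly spread over the libraries. Cluster 8, led by Saa3, held 0.530% of saline, 13.3% of vaccine and 16.9% of combination macrophage-like cells. Cluster 19, led by Cd209f, Lyve1 and Cd163, held 7.39%, 0.618% and 0.224%. Cluster 5, led by Spp1, Fabp5, Mmp12 and Trem2, held 48.3%, 17.1% and 15.995%, and cluster 4, led by Cd300e and Slamf9, held 4.80%, 33.3% and 34.6%. A cluster found mostly in 1 library may be a trait of that library rather than a cell type. Within cluster 5 alone, Saa3 was at 210.3 CPM with the vaccine and 17.7 CPM with saline, while few UMIs remained of Retnla, with a log2 ratio of −6.62 [−9.99 to −5.09], and of Cd209f, with one of −3.46 [−9.36 to −1.48]. Lcn2 there was at 2.70 CPM and 1.17 CPM.

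**Figure D2:**
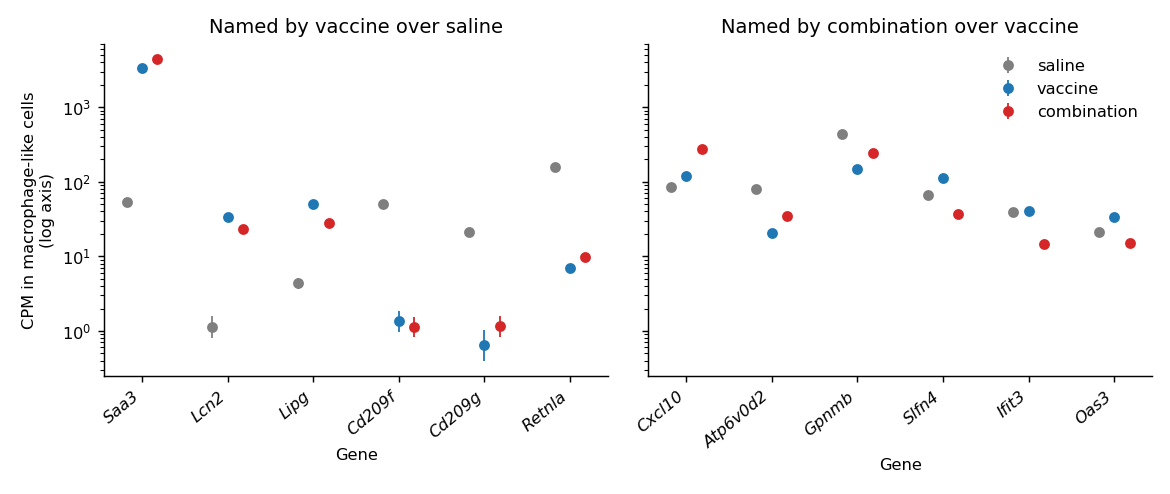
CPM of the genes named in macrophage-like cells (log y axis) for vaccine over saline (left) and combination over vaccine (right), with points for the saline, vaccine and combination library and exact 95% counting intervals as bars. Saa3 lies at 53.3 CPM with saline and 3317 CPM with the vaccine, and Slfn4 at 111.5 CPM with the vaccine and 36.9 CPM with the combination.

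Several gene groups separated the vaccine and saline macrophage-like cells. In the alternative macrophage list, 1 of 19 measured members was at least 1.5-fold higher, 12 were lower and 6 were neither, with a median log2 ratio of −0.84 [−0.90 to −0.77]. Its lowest members were Cd209f at −5.23 and Retnla at −4.50, while Il10, an anti-inflammatory cytokine, was at 2.47. The tumour macrophage lipid and tissue program had 0 higher and 14 lower of 20 members, a median of −0.91 [−0.93 to −0.90] and as lowest members the tetraspanin Cd9 at −1.97 and the matrix protein Spp1 at −1.96. Cell cycle genes had 17 of 20 lower and a median of −0.95, with Cdc20 at −1.48 and Ccna2 at −1.30. Of 25 interferon gamma response genes, 11 were higher and 0 lower, at a median of 0.56 [0.47–0.61], with the GTPases Irgm2 at 1.12 and Gbp3 at 1.07. Type I interferon response genes had a median of 0.30 with 5 of 23 higher, among them Ifi44 at 1.34 and Rsad2 at 1.19. Percentiles among random lists were 0 for the alternative list, 100 for interferon gamma and 99.5 for type I interferon.

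Inflammatory macrophage genes had a median of 0.44 with 7 of 16 higher and 2 lower. The formyl peptide receptor Fpr2 was at 2.52 and the cytokine Il1b at 2.08, while Slc7a2 was at −1.28. In the Toll-like receptor and NF-kB list, 7 of 21 members were higher and 0 lower, with a median of 0.38. The feedback inhibitors Tnfaip3 and Irak3 led it at 2.34 and 1.91. The leukocyte attracting chemokines went both ways, with 4 of 18 higher, led by Ccl4 and Cxcl1 at 1.90 each, and 8 lower, led by the eosinophil attractant Ccl24 at −3.66 and the B cell attractant Cxcl13 at −3.59. MHC class I presentation had a median of 0.29 with 3 of 19 higher, and MHC class II presentation a median of −0.24 at a percentile of 7.68, so it was not set apart from random lists. Hypoxia and glycolysis was at −0.41 with 1 of 20 higher and 4 lower. Checkpoint ligands had a median of 0.02, but Cd274, which encodes PD-L1, was at 118.7 CPM [114.8–122.7] with the vaccine and 61.4 CPM [58.7–64.1] with saline.

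Without clusters 8 and 19 the alternative list was at −0.64, the lipid and tissue program at −0.92 and interferon gamma response at 0.75. Within cluster 5 alone they were at −0.68, −0.33 and 0.53, and the cell cycle list was at −0.40. The direction was thus the same in each of these sums. Cluster 5 is led by members of the lipid list, so the lipid median within it does not show whether the difference lay in the mix of clusters. For macrophage-like and monocyte-like cells together, the alternative list was at −0.94, the lipid list at −0.78 and interferon gamma response at 0.50.

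In monocyte-like cells of the vaccine library the rule named Gdf15, Rgs1 and Tnfaip3 as higher. Gdf15, a stress-induced cytokine, was at 473 CPM [460.1–487.0] with the vaccine and 50.4 CPM [45.9–55.3] with saline. Rgs1, a regulator of chemokine receptor signalling, was at 1269 CPM and 189 CPM, and Tnfaip3, an inhibitor of NF-kB, at 424 CPM and 76.8 CPM. Lower were Retnla at 1.48 CPM and 54.1 CPM, Ccl24 at 5.52 CPM and 39.3 CPM, and the ribonuclease Ear2 at 3.94 CPM and 24.2 CPM. Macrophage RNA estimated from C1q genes would give 3.33 CPM and 53.6 CPM of Retnla and 3.77 CPM and 34.1 CPM of Ccl24. For Ear2 it would give 2.59 CPM and 8.88 CPM. The estimate counts all C1q RNA of monocyte-like cells as macrophage RNA. C1q genes there reached 48.3% with the vaccine and 34.4% with saline of their macrophage-like level. In CD8 T-like cells they reached 3.34% and 2.64%. The estimate may thus be too high, and it leaves undecided whether the Retnla and Ccl24 differences belong to monocyte-like cells. The chemokine list had a median of 0.44 here with 7 of 16 higher, led by Ccl4 and Cxcl1 at 1.81 each, and the inflammatory list one of 0.38, led by Ptgs2 at 1.93 and Il6 at 1.64. The alternative list had a median of 0.07 and the lipid list one of 0.15. With doublets kept, the chemokine and lipid medians of monocyte-like cells turned to −0.27 and −0.43.

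The Toll-like receptor and NF-kB list, measured there after seeing the data, had 8 of 13 members higher in CD8 T-like and 8 of 14 in CD4 T-like cells, with medians of 0.63 and 0.86. Named CD8 T-like genes included the transcription factors Maff at 22.99 CPM [19.7–26.6] with the vaccine and 4.94 CPM [3.67–6.52] with saline, and Tgif2 at 20.3 CPM and 3.85 CPM. The histone gene Hist1h3e was at 20.3 CPM and 51.9 CPM. In CD4 T-like cells Irf4, a transcription factor induced by T cell receptor signals, was at 58.2 CPM [51.0–66.2] and 10.5 CPM [8.06–13.4], and Mir155hg, the noncoding host gene of microRNA-155, at 21.4 CPM and 3.49 CPM. The activity-regulated gene Arc was at 4.23 CPM and 36.3 CPM. Checkpoint receptor genes had a median of 0.48 in CD4 T-like cells with 2 of 12 higher, Ctla4 at 1.24 and Nr4a2 at 1.10, and a median of 0.21 in CD8 T-like cells with 3 of 14 higher and 2 lower, at a percentile of 94.9. There Ctla4 was at 1.68, and Cd160 and Cxcr6 at −0.79 and −0.64.

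Different sub-clusters held most CD8 and CD4 T-like cells in saline and vaccine. CD8 T-like cells lay mostly in sub-cluster 2 with saline (74.2%) and in sub-cluster 1 with the vaccine (80.6%) and the combination (63.5%). Sub-cluster 1 is led by Ccl4, Ccl5, Cxcr4 and the stress gene Ddit3, and sub-cluster 2 by Trbv12-2 and Gzmk. CD4 T-like cells lay mostly in sub-cluster 3 with saline (88.5%), led by Ifitm1 and Ass1, and in sub-cluster 4 with the vaccine (82.7%) and the combination (67.7%), led by Furin, Nfkbiz, Nfkbia, Cebpb and the heat shock gene Hspa1a. Genes of the NF-kB and stress lists thus stand among those that define sub-cluster 4.

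Saa3, Ccl8, Cd63 and Retnla were also named in T-like cells, where free macrophage RNA was estimated beside them. In CD8 T-like cells Saa3 was at 208.6 CPM with the vaccine and 10.9 CPM with saline, and the macrophage RNA estimated from C1q genes would give 110.9 CPM and 1.41 CPM. Ccl8, a monocyte attractant, was at 35.3 CPM and 104.9 CPM, with an estimated 20.6 CPM and 53.9 CPM from macrophages, and the tetraspanin Cd63 at 12.4 CPM and 33.8 CPM, with 8.86 CPM and 23.8 CPM. In CD4 T-like cells Saa3 was at 246 CPM and 11.8 CPM, Ccl8 at 33.1 CPM and 114.8 CPM, and Retnla had 3 UMIs with the vaccine and 172 UMIs with saline. C1q genes reached 262 CPM, 289 CPM and 268 CPM in saline, vaccine and combination CD8 T-like cells, which is 2.64%, 3.34% and 3.08% of their level in macrophage-like cells. The estimate rests on these genes alone, so a level above it, as for Saa3, does not show that T-like cells express the gene.

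Effector, memory and help lists of T-like cells had medians between −0.21 and 0.05 in the vaccine library. Their percentiles among random lists were 1.245 for cytotoxic effector, 1.13 for naive and memory genes and 64.8 for Th1 and T cell help. Cytotoxic effector genes in all T-like cells had a median of −0.18 with 2 of 17 higher and 2 lower. Among CD8 T-like cells the chemokines Ccl4 and Ccl3 were at 1.41 and 1.04, Gzmc at −2.01 and Klrk1 at −0.55. Th1 and T cell help genes were at 0.05 with 1 of 14 higher and 0 lower, and naive and memory genes at −0.21 with 2 of 11 higher and 1 lower. In CD8 T-like cells the naive gene Klf2 was at 0.98, Ccr7 at 0.85 and Il7r at −0.50. T cell costimulation was at −0.08 with 3 of 11 higher, among them Slamf1 and Icos in CD8 T-like cells at 1.09 and 0.98. The regulatory T cell program was at −0.13 with 4 of 13 higher and 3 lower, with Il10 at 13.4 CPM and 0.998 CPM in CD4 T-like cells. MHC class I presentation was at 0.06 and hypoxia and glycolysis at −0.11. Type I interferon genes had a median of 0.00 in all T-like cells and of 0.49 with 9 of 22 higher in CD8 T-like cells, the interferon-responding sub-cluster being counted only in the former. Cell cycle genes were at 0.25 with 2 of 20 higher.

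In dendritic-like cells of the vaccine library, relative to saline, interferon gamma response was at 0.46 with 10 of 25 higher and 1 lower, led by the GTPases Iigp1 at 1.23 and Tgtp1 at 1.06, and type I interferon response at 0.43 with 3 of 23 higher, 0 lower and 20 neither. Leukocyte attracting chemokines were at −0.59 with 3 of 17 higher and 9 lower, with Ccl4 at 1.40, Ccl24 at −2.88 and Ccl8 at −1.78. Dendritic cell maturation had 5 of 18 higher and 3 lower and a median of 0.03. In it the costimulatory ligand Tnfsf9 was at 1.27 and Cd83 at 1.16, whereas Ccl17, which attracts Ccr4-bearing T cells, was at −2.95. Migratory cells, whose markers Ccr7, Fscn1, Ccl22 and Socs2 are in this list, were 203 of 936 saline and 107 of 717 vaccine dendritic-like cells. Medians of dendritic-like cells can thus also depend on the mix of subsets, which was not separated. MHC class II presentation was at −0.02 in dendritic-like cells and 0.36 in B-like cells, the latter from 10 vaccine cells. In NK-like cells the Toll-like receptor and NF-kB list was at 0.82, cell cycle at −0.59 and cytotoxic effector at −0.01.

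The dissociation stress list, of early-response and heat shock genes induced by tissue digestion and also by cell activation, was higher with the vaccine by 0.68 in macrophage-like, 0.59 in monocyte-like, 0.87 in dendritic-like, 0.47 in CD8 T-like, 0.41 in CD4 T-like and 0.16 in NK-like cells. It was also higher in melanoma-like cells, at 1.38 with 15 of 19 members higher, but lower in neutrophil-like cells, at −0.48 with 0 of 18 higher and 8 lower (−0.17 with size factors), and in B-like cells, at −0.35 with 3 of 16 higher and 6 lower. Plasmacytoid dendritic-like cells were at −0.12 (0.05 with size factors). In macrophage-like cells Fosb was at 1.61 and Zfp36 at 1.51. The list for free RNA from tumour cells went both ways, at −0.51 in macrophage-like (4 of 10 lower) and −0.56 in CD8 T-like cells (2 of 5 lower), but 0.20 in monocyte-like (2 of 6 higher) and 0.45 [−0.06 to 0.94] in type 2 dendritic-like cells (1 of 5 higher). In CD4 T-like cells it was at −0.26 [−0.60 to 0.14] with 0 of 5 past 1.5-fold. Mitochondrial transcripts were at 0.02 in macrophage-like and −0.26 in CD8 T-like cells.

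The second comparison, combination over vaccine, asks what differed when the TIGIT antibody was added. The median log2 ratio of the type I interferon list was below 0 in macrophage-like, monocyte-like, dendritic-like and T-like cells. The median of the cell cycle list was above 0 in T-like cells as a whole, with 5 of 20 members at least 1.5-fold higher. A small cycling sub-cluster held more of these cells, and was 1.80% of kept cells with the combination and 1.43% with the vaccine. The CD8 and CD4 T-like classes leave that sub-cluster out, so their smaller medians do not show how much these subsets cycled. Macrophage-like Ifit3, an interferon-induced antiviral gene, was at 14.6 CPM [13.4–15.9] with the combination and 40.1 CPM [37.8–42.5] with the vaccine, and at 38.9 CPM with saline. In NK-like cells Gzmb, the granule protease granzyme B, was at 1927 CPM [1808–2051] and 1249 CPM [1166–1337], and Ifng, the cytokine interferon gamma, at 863 CPM [784.2–947.7] and 528 CPM [474.3–586.1]. These NK-like values came from 140 and 145 cells.

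Type I interferon response genes had a median log2 ratio of −0.69 [−0.74 to −0.64] in macrophage-like cells, with 0 of 23 members higher, 15 lower and 8 neither. The lowest were Ifi44 at −2.19 and Ifit3b at −1.57, and Rsad2 was at 0.11. Median ratios in the other classes were −0.41 with 7 lower in monocyte-like cells, −0.60 with 12 of 23 lower in dendritic-like cells and −0.48 [−0.56 to −0.39] with 8 of 22 lower in all T-like cells. CD8 T-like cells alone were at −0.43 and CD4 T-like cells at −0.39, with Ifit3b at −1.57 in the former and Ifit3 at −2.39 in the latter. NK-like cells were at 0.14 [−0.22 to 0.35], with 7 of 24 members measured and none past 1.5-fold. Within cluster 5 the macrophage-like median was −0.96 with 0 higher and 18 lower. Relative to saline, the combination was at −0.35 in macrophage-like and −0.43 in all T-like cells, which include an interferon-responding sub-cluster of 270 saline, 140 vaccine and 76 combination cells.

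The interferon gamma response list also had medians below 0. Ifng itself in T-like cells was at 631 CPM with the combination and 644 CPM with the vaccine. T-like cells were 20.3% and 29.1% of cells in the same order, so these levels do not show an equal supply of Ifng. The list was at −0.42 [−0.49 to −0.37] in macrophage-like cells with 1 of 25 higher and 7 lower, at −0.42 in monocyte-like and at −0.59 in dendritic-like cells with 12 of 24 lower. The GTPase Tgtp1 was lowest, at −1.57 in macrophage-like and −1.48 in dendritic-like cells. The 1 higher member in macrophage-like cells was the T cell attractant Cxcl10, at 274 CPM [268.9–279.6] with the combination and 117.9 CPM [114.0–121.9] with the vaccine. MHC class I presentation was at −0.21 in macrophage-like and dendritic-like cells, with no member past 1.5-fold in the former, and −0.005 in T-like cells. MHC class II presentation was at −0.01 in macrophage-like and 0.24 in monocyte-like cells.

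Besides Cxcl10, which had the highest ratio, the rule named Gpnmb and Atp6v0d2 as higher in combination macrophage-like cells. Gpnmb, a glycoprotein of lipid-laden macrophages, was at 246 CPM [241.1–251.2] and 148.6 CPM [144.2–153.1], and 445 CPM with saline. Atp6v0d2, a subunit of the lysosomal proton pump, was at 35.1 CPM and 20.3 CPM, and 80.9 CPM with saline. The lipid and tissue program had a median of 0.27 with 2 of 20 higher and 0 lower. Lower were Slfn4, an interferon-induced gene of myeloid cells, at 36.9 CPM [34.9–38.9] and 111.5 CPM [107.6–115.4], and Oas3, an antiviral enzyme, at 14.96 CPM and 33.4 CPM. The alternative list was at 0.00, inflammatory genes at −0.02, Toll-like receptor and NF-kB at −0.10, chemokines at −0.07 and cell cycle at 0.01. Slfn4 lies on chromosome 11 at 83175186–83190216 on the plus strand (ENSMUSG00000000204), Ifit3 on chromosome 19 at 34583531–34588731 on the plus strand (ENSMUSG00000074896) and Cxcl10 on chromosome 5 at 92346638–92348889 on the minus strand (ENSMUSG00000034855). Each is protein-coding.

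Monocyte-like cells of the combination had higher Ccl24 at 35.7 CPM [31.7–40.0] and 5.52 CPM [4.17–7.17], the glycoprotein Lrg1 at 20.8 CPM and 5.52 CPM, and the chitinase-like Chil3 at 231 CPM and 79.0 CPM. Lower were Slfn4 at 97.1 CPM [90.5–104.1] and 309 CPM [298.5–320.3], Lhfpl2 at 6.58 CPM and 22.97 CPM, and the small heat shock gene Hspb1 at 8.28 CPM and 41.2 CPM, whose order turned at a clustering resolution of 2. Dendritic cell maturation was at −0.33 in dendritic-like cells with 0 of 18 higher and 1 lower, Pdcd1lg2, which encodes PD-L2, at −0.94.

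Cell cycle genes in all T-like cells were at 0.37 [0.29–0.45] with 5 of 20 higher and 0 lower. Within CD8 T-like cells the median was 0.13 with 2 of 16 higher, and within CD4 T-like cells 0.06 with 1 of 13 higher. A cycling sub-cluster, counted only in all T-like cells, held 185 of 5382 saline, 211 of 4301 vaccine and 250 of 2809 combination T-like cells. Its CD8 to CD4 ratio of 14.6 lay below the CD8 threshold of 16, so the CD8 and CD4 T-like medians leave these cells out. After thinning each cell to 1000 UMIs, Mki67, a marker of dividing cells, had a UMI in 3.04% [2.59–3.55] of saline, 4.39% [3.78–5.07] of vaccine and 7.13% [6.17–8.19] of combination T-like cells, and without thinning in 6.63%, 8.56% and 12.5%. Its level was 62.5 CPM, 106.6 CPM and 167 CPM. In macrophage-like cells, which divide themselves, the thinned share was 5.01%, 2.85% and 3.05%, so no background share free of expression was available for Mki67. The thinning left out 218, 247 and 216 T-like cells, and the median depth of those used was 3326, 2984 and 2909 UMIs, against 8979, 5413 and 5754 UMIs in macrophage-like cells.

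Cebpb, a transcription factor of the stress response, was at 139.2 CPM [128.6–150.4] with the combination and 387 CPM [373.4–401.2] with the vaccine in CD8 T-like cells. Ifit1 was at 9.38 CPM and 22.5 CPM there and at 13.2 CPM and 38.6 CPM in CD4 T-like cells, and Ifit3 at 11.8 CPM and 25.6 CPM in CD8 T-like cells. In CD4 T-like cells Tnfsf11, which encodes the cytokine RANKL, was at 8.12 CPM and 23.1 CPM, and the pseudokinase Trib1 at 23.1 CPM and 60.5 CPM. Higher were the membrane protein Ifitm1 at 87.3 CPM and 47.5 CPM in CD8 T-like and 238 CPM and 115.4 CPM in CD4 T-like cells, and in CD4 T-like cells the metallothionein Mt1 at 118.7 CPM and 55.7 CPM and the hypoxia gene Bnip3 at 29.9 CPM and 14.2 CPM. Ptgds at 20.1 CPM and 5.68 CPM and Cd63 at 32.9 CPM and 12.4 CPM were higher in CD8 T-like cells, and Ptgds belongs to the tumour RNA list.

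That list, free RNA from tumour cells, was higher with the combination by 1.72 in CD8 T-like cells and 1.37 in CD4 T-like cells, with 5 of 5 measured members higher in each, and by 0.37 in macrophage-like cells and 0.32 in monocyte-like cells, where 2 of 6 were higher and 1 lower. Melanoma markers together were at 34.3 CPM, 24.8 CPM and 77.9 CPM in saline, vaccine and combination T-like cells. Melanoma-like cells were 1.05%, 0.671% and 1.32% of kept cells. Mitochondrial transcripts in CD8 T-like cells were at 0.30, and the dissociation stress list was at −0.28 in macrophage-like, −0.36 in CD8 T-like and −0.19 in dendritic-like cells.

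Other T cell groups had medians between −0.20 and 0.13 for combination over vaccine. Though small, some lay at the edges of the random lists. Percentiles were 0.07 for Th1 and T cell help, 0.14 for checkpoint receptors, 0.155 for naive and memory genes and 99.3 for hypoxia and glycolysis. They were 54.05 for cytotoxic effector, 3.925 for the regulatory T cell program and 12.1 for costimulation. Cytotoxic effector genes in all T-like cells were at 0.02 with 1 of 16 higher, with Gzma at 0.53 in CD8 T-like cells. Checkpoint receptors were at −0.17 with none past 1.5-fold, Th1 and T cell help at −0.16 with 1 of 14 lower, regulatory T cell program at −0.10, costimulation at −0.06, hypoxia and glycolysis at 0.13 and naive and memory genes at −0.20 with 1 of 11 lower, Ccr7 at −1.06 in CD8 T-like cells. Tcf7, a factor of naive and stem-like T cells, had a UMI in 11.2%, 9.37% and 7.79% of thinned saline, vaccine and combination T-like cells against 0.330%, 0.199% and 0.217% of macrophage-like cells, in 28.1%, 22.97% and 18.1% of T-like cells without thinning, and its level was 111.4 CPM, 96.4 CPM and 78.0 CPM. In NK-like cells cytotoxic effector genes were at 0.35 [0.24–0.44] with 4 of 17 higher and 0 lower, at a percentile of 100. Ifng was at 0.71 there. Gzmf had 64 UMIs with the combination and 0 with the vaccine in NK-like cells, where a count of 0 allows up to 3. That bound covers the counting of UMIs only, and the number of cells that held them is not given.

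**Figure D3:**
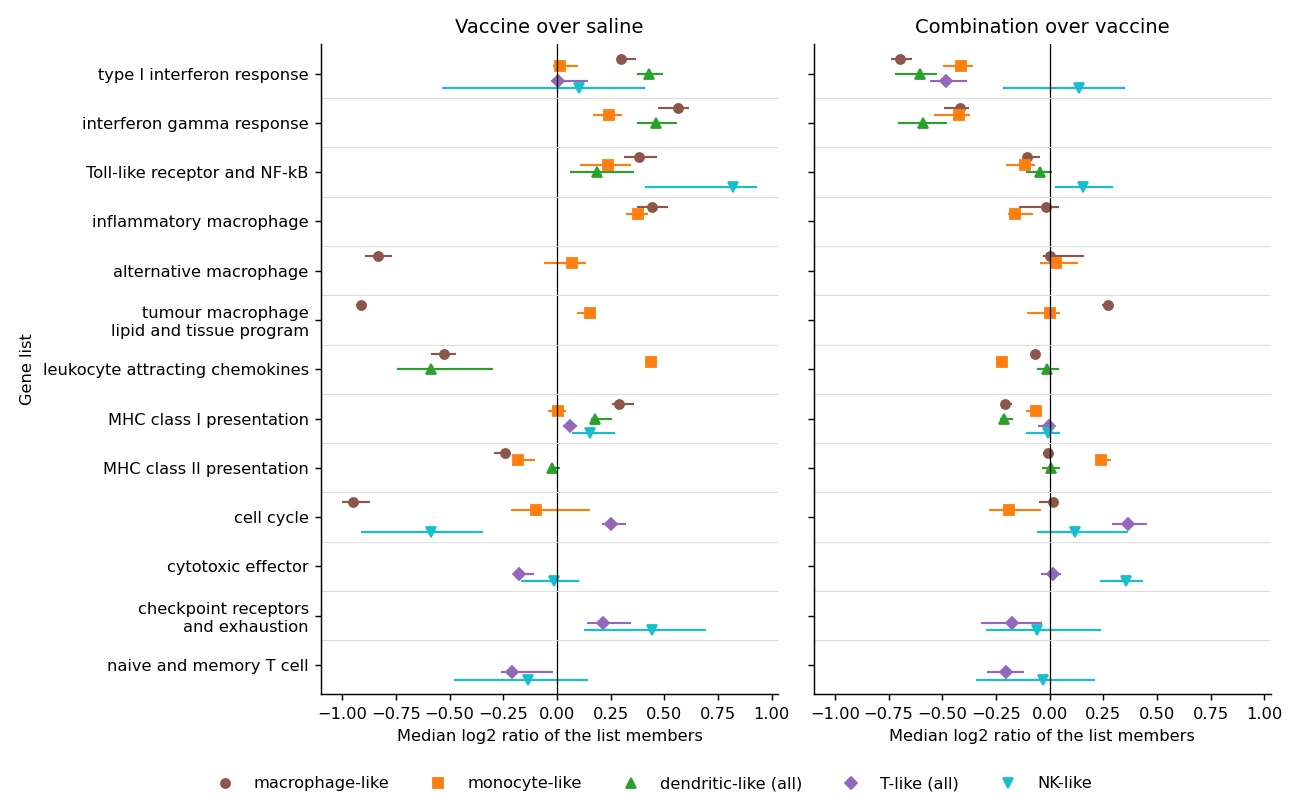
Median log2 ratio of the measured members (x axis) of 13 gene lists (y axis) in macrophage-like, monocyte-like, dendritic-like, T-like and NK-like cells for vaccine over saline (left) and combination over vaccine (right), with bars for the interval from counting error. The type I interferon list in macrophage-like cells lies at 0.30 on the left and −0.69 on the right.

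The receptor that the antibody targets and its partners were measured in each library. Tigit (chromosome 16, 43648867–43664146, minus strand, ENSMUSG00000071552) was at 99.0 CPM [94.6–103.6] in saline, 117.3 CPM [111.7–123.1] in vaccine and 82.7 CPM [76.8–89.0] in combination T-like cells. Thinned to 1000 UMIs, 9.51%, 10.1% and 8.10% of T-like cells had a Tigit UMI, against 0.165%, 0.133% and 0.163% of macrophage-like cells, and 26.1%, 26.6% and 20.1% of T-like cells without thinning. By subset, CD8 T-like cells had 106.2 CPM, 122.8 CPM and 95.1 CPM, CD4 T-like cells 89.7 CPM, 113.4 CPM and 75.2 CPM, and NK-like cells 133 CPM, 136 CPM and 128 CPM. Regulatory T-like cells had 36, 21 and 8 Tigit UMIs, too few to rank. Cd226, the activating receptor that competes for the same ligands, was at 110.9 CPM, 111.5 CPM and 123.8 CPM in T-like cells. The ligand gene Pvr was at 16.4 CPM, 27.1 CPM and 23.8 CPM in macrophage-like and 24.99 CPM, 40.6 CPM and 36.0 CPM in dendritic-like cells. Nectin2 was at 2.03 CPM, 2.93 CPM and 3.98 CPM in macrophage-like and 11.1 CPM, 5.96 CPM and 4.98 CPM in dendritic-like cells. The TIGIT axis list had a median of 0.01 in T-like cells in both of these comparisons, and one of 0.52 [−0.15 to 0.64] in macrophage-like cells for vaccine over saline, with 1 of 7 higher and 2 lower.

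The CPM of Gzmb, Ifng and Pdcd1 was higher in T-like cells with the vaccine than with saline. The thinned share of T-like cells with an Ifng UMI hardly differed. With the combination Pdcd1 was back at the saline level in all T-like cells. In CD4 T-like cells it was at 32.3 CPM, 45.5 CPM and 39.7 CPM with saline, vaccine and combination. Gzmb (chromosome 14, 56258838–56262260, minus strand, ENSMUSG00000015437) was at 434 CPM, 589 CPM and 611 CPM in T-like cells, with a UMI in 21.9%, 26.9% and 28.8% of thinned cells against 0.528%, 0.730% and 0.921% of macrophage-like cells. Ifng was at 549 CPM, 644 CPM and 631 CPM, with a UMI in 34.6%, 34.95% and 37.7% of thinned T-like cells against 1.06%, 0.885% and 0.759% of macrophage-like cells, and in 61.8%, 56.1% and 58.7% of T-like cells without thinning. Pdcd1, which encodes PD-1, was at 38.4 CPM, 53.1 CPM and 38.5 CPM in T-like cells, and Cd274 at 61.4 CPM, 118.7 CPM and 89.1 CPM [86.04–92.1] in macrophage-like and 82.1 CPM, 189 CPM and 104.3 CPM in monocyte-like cells. Foxp3, the factor that defines regulatory T cells, was at 5.43 CPM, 2.18 CPM and 5.76 CPM in T-like cells. Havcr2 had a UMI in 1.61%, 2.61% and 2.78% of thinned T-like cells and 2.44%, 2.30% and 1.45% of macrophage-like cells, and its level was 19.0 CPM, 32.5 CPM and 31.3 CPM against 21.1 CPM, 20.4 CPM and 15.3 CPM; macrophages express Havcr2, so they give no background share for it.

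The third comparison, combination over saline, covers the vaccine and the antibody together. Macrophage-like cells again had more Saa3 and less Cd209f than with saline. In all T-like cells together the cell cycle list had a median above 0 and the type I interferon list one below 0. Melanoma markers together were also higher in CD8 T-like cells, at 76.6 CPM with the combination and 35.7 CPM with saline. CD4 T-like cells had them at 100.8 CPM and 39.4 CPM. T-like cells were at 0.509 [0.486–0.533] times and phagocyte-like cells at 1.57 [1.51–1.63] times their saline shares. Saa3 was at 4407 CPM [4385–4428] in combination macrophage-like cells, and Lyve1, a hyaluronan receptor of resident macrophages, at 1.57 CPM [1.19–2.03] with the combination and 61.5 CPM [58.8–64.2] with saline. Cell cycle genes in T-like cells were at 0.65 [0.57–0.74], with 12 of 20 higher and 0 lower, but at 0.04 in CD8 and 0.20 in CD4 T-like cells alone. Type I interferon genes were at −0.43 in all T-like cells, 0.06 in CD8 and −0.13 in CD4 T-like cells. The cycling and interferon-responding sub-clusters are counted only in all T-like cells, so the CD8 and CD4 T-like values alone do not show how these subsets differed.

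Macrophage-like Lcn2 was at 23.1 CPM and 1.14 CPM and Igsf9 at 21.2 CPM and 1.94 CPM. Cd209f was at 1.14 CPM and 51.1 CPM and Cd209g at 1.16 CPM and 21.4 CPM. Lcn2 was at 2094 CPM in combination neutrophil-like cells, and free RNA from these was not estimated. Within cluster 5, Saa3 was at 589 CPM and 17.7 CPM, Lyve1 at 0.572 CPM and 11.6 CPM, and Igsf9 at 1.94 CPM and 1.43 CPM, so the Igsf9 difference lay mainly in other clusters. The alternative list was at −0.79 with 1 of 18 higher and 11 lower, cell cycle at −0.95 with 18 of 20 lower, inflammatory genes at 0.58 with 8 of 16 higher and 3 lower, and Toll-like receptor and NF-kB genes at 0.44. The lipid and tissue program was at −0.64 in all macrophage-like cells, −0.66 without clusters 8 and 19 and 0.01 within cluster 5, which its own members lead. Interferon gamma response was at 0.04. The dissociation stress list was also above 0 in this comparison. It was at 0.31 with 6 of 19 higher and 0 lower in phagocyte-like cells, and at 0.69 with 10 of 19 higher in dendritic-like cells.

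Monocyte-like cells had Saa3 at 619.6 CPM [602.7–636.9] and 93.5 CPM [87.2–100.03], Tnfaip3 at 410.1 CPM and 76.8 CPM, and Gdf15 at 252 CPM and 50.4 CPM. Lower there were Retnla at 1.22 CPM and 54.1 CPM, the lysozyme gene Lyz1 at 14.4 CPM and 58.7 CPM, and Fam71a at 7.07 CPM and 24.9 CPM. Macrophage RNA would give 1935 CPM and 18.3 CPM of Saa3 and 4.29 CPM and 53.6 CPM of Retnla in monocyte-like cells. For Saa3 with the combination the estimate exceeds the measured level, so counting all C1q RNA there as macrophage RNA gives too much. The estimate therefore does not decide whether these 2 differences belong to monocyte-like cells. In CD8 T-like cells Maff was at 22.3 CPM and 4.94 CPM and Chtf8, of a replication factor complex, at 9.82 CPM and 23.1 CPM. CD4 T-like cells had Irf4 at 37.6 CPM and 10.5 CPM, Ifit1 at 13.2 CPM and 53.7 CPM, and Arc at 7.26 CPM and 36.3 CPM. Saa3 was at 368 CPM in CD8 and 441 CPM in CD4 T-like cells, of which macrophage RNA would give 135.6 CPM and 168.1 CPM. The chemokine gene Cxcl2, at 80.7 CPM in CD8 and 119.6 CPM in CD4 T-like cells, lay at the level that macrophage RNA would give, 93.4 CPM and 115.8 CPM. Ccl12 at 11.1 CPM and 38.0 CPM in CD8 T-like cells also lay near it, with 13.8 CPM and 32.2 CPM, Ccl8 was at 29.7 CPM there, and Retnla had 5 UMIs in CD4 T-like cells.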

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

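Of the tests below, those of cells with at least 2000 UMIs, of the dissociation stress list and of free RNA were chosen only after the result was seen; the Toll-like receptor and NF-kB list was also extended to T-like and NK-like cells at that point. A free RNA test planned earlier, on CD8 T-like cells without any UMI of C1qa, C1qb, C1qc, Apoe or Lyz2, was dropped: 388 saline, 535 vaccine and 298 combination cells had none, where chance alone gives 402.1, 551.5 and 319.2, so these cells are not free of such RNA. Its replacement takes the free RNA estimated from those genes off each list member, with macrophage-like cells, macrophage-like and monocyte-like cells or all kept cells outside the T lineage as its source, and gives the source that left the least. The 3 patterns weighed first came from the shares and gene lists, and the results after them were picked out by fixed rules.

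A lower share of T-like cells with the vaccine and with the combination than with saline runs against what a T cell vaccine might be thought to bring, although the shares are relative and more phagocytes alone would lower them. Barcodes lost to the filters or left unnamed are argued against as the whole cause, since over all barcodes the share with more T cell than macrophage marker UMIs had a combination over saline ratio of 0.596 [0.574–0.619]. Loss of T cells below the 500 UMI minimum stays open: among cells with at least 2000 UMIs the ratio was 0.479 [0.455–0.505], but T-like cells had a lower median depth with the combination (2777 UMIs) than with saline (3268 UMIs), so a loss of small cells could lower that ratio too and the bound of 0.8 set for it excluded nothing. A difference between single libraries or their handling, such as digestion or bead yield, cannot be told apart from the treatment with 1 library per group. An effect of the treatments on T cell entry, survival or phagocyte numbers also remains open and untested.

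The Toll-like receptor and NF-kB list was higher with the vaccine than with saline in macrophage-like, monocyte-like, dendritic-like, CD8 T-like, CD4 T-like and NK-like cells. Free RNA from phagocytes, at the amount estimated, is argued against as the whole cause in CD8 T-like cells, since after its subtraction the median was 0.58 [0.49–0.75], against 0.63 before. The estimate from C1q genes alone gave 110.9 CPM of the 208.6 CPM of Saa3 in vaccine CD8 T-like cells. For Cxcl2 with the combination it did not fall short, at 93.4 CPM against 80.7 CPM. A larger amount of free RNA was therefore not excluded. Stress from tissue dissociation fits the values and stays open: the dissociation stress list was above 0 in each of the 6 classes, the lowest median being 0.16 [0.07–0.31] in NK-like cells. In NK-like, CD8 and CD4 T-like cells the stress medians of 0.16, 0.47 and 0.41 were below the NF-kB medians of 0.82, 0.63 and 0.86, while in the macrophage-like, monocyte-like and dendritic-like cells the order was the other way round, and outside the 6 classes the stress list was lower in neutrophil-like (−0.48, or −0.17 with size factors) and B-like cells (−0.35) and higher in melanoma-like cells (1.38). A response to CpG, which acts through Toll-like receptor 9, stays open as an untested hypothesis, and early-response genes belong to both.

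For combination over vaccine, the type I interferon list had a median below 0 in macrophage-like, monocyte-like, dendritic-like, CD8 T-like and CD4 T-like cells. Members at least 1.5-fold lower were 15 of 23, 7 of 23, 12 of 23, 8 of 22 and 7 of 20 in the same order. NK-like cells were at 0.14 [−0.22 to 0.35] with only 7 members measured. A shift of cells between clusters is argued against as the whole cause in macrophage-like cells only. Monocyte-like cells were a single cluster, so their median is that of the whole class and could not weigh such a shift. Within 7 single clusters, that of the monocyte-like cells included, the middle median was −0.58, and each median was below 0. That is past the −0.35 that is 50 percent of the value in all macrophage-like cells. None of these clusters is led by genes of the list, so fewer interferon-high cells spread within them were not weighed. Dendritic-like cells and the interferon-responding T-like sub-cluster, of 270 saline, 140 vaccine and 76 combination cells, were not part of this test. Free RNA, at the amount estimated, is argued against as the whole cause in CD8 T-like cells, since after its subtraction the median was −0.38 [−0.58 to −0.30], against −0.43 before. A larger amount was not excluded here either. The dissociation stress list was also below 0 in this comparison, at −0.34 in phagocyte-like and −0.19 in dendritic-like cells, and its relation to the interferon list was not tested. What stays open is a difference between the single libraries, for instance in the hours between the last CpG injection and collection, which the labels give only in days. An effect of TIGIT blockade on interferon response genes also stays open and was not tested.

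The leukocyte attracting chemokines list for vaccine over saline had opposite directions in the phagocyte classes, −0.53 in macrophage-like and 0.44 in monocyte-like cells (−0.27 with doublets kept); the difference was not tested. The tumour macrophage lipid and tissue program did the same, with −0.91 in macrophage-like and 0.15 in monocyte-like cells (−0.43 with doublets kept), and this difference was not tested either. Barcodes over the mitochondrial limit, which the comparisons leave out, were 5.73% of the combination library against 2.71% with saline and 2.33% with the vaccine, and they held melanoma markers at 1577 CPM, 1712 CPM and 1619 CPM in the same order.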

How the results depend on the processing

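The tests in this part added only after results were seen were the automatic doublet threshold, cells with at least 2000 UMIs, the low-UMI sub-cluster counted as T-like, the joined or restricted classes and the stress and Toll-like receptor lists in further classes. Of 371 alternative values of shares, 349 kept their direction, as did 359 of 360 for genes named by ratio, 654 of 710 for genes always named, 1431 of 1584 for gene lists (685 of 694 for lists set apart from random lists) and 255 of 335 for shares of cells with a UMI. The T-like share ranged over 0.516–0.789 for vaccine over saline and 0.479–0.646 for combination over saline, and the phagocyte-like share over 1.27–1.39 and 1.51–1.66. Limits included the boundary between macrophage-like and monocyte-like cells, the small classes and the joint clustering of the libraries. With each library clustered alone, 8 of 35 share values went in the other direction. Among them was the T-like ratio of combination over vaccine, at 1.252 instead of 0.696. No B-like, plasmacytoid, regulatory T-like or type 1 dendritic-like cells were found in the vaccine library clustered alone, no regulatory T-like cells with doublets kept or at least 500 genes, and no type 1 dendritic-like cells at resolution 0.5. Where a value below turned or moved, the cause was not tested.

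Each library clustered alone gave T-like ratios of 0.516 (vaccine over saline), 1.252 (combination over vaccine, turned) and 0.646 (combination over saline), CD4 T-like ratios of 1.58 (vaccine over saline) and 1.12 (combination over saline), and monocyte-like ratios of 0.396 (vaccine over saline) and 1.99 (combination over vaccine). Resolution 2 gave T-like ratios of 0.640 (vaccine over saline) and 0.773 (combination over vaccine), monocyte-like ratios of 0.494 and 1.58 in that order, and log2 ratios of 0.21 for monocyte-like Hspb1 (combination over vaccine), 0.51 for monocyte-like Gzmb (vaccine over saline) and 0.078 for macrophage-like Ifng (combination over saline). Resolution 0.5 gave phagocyte-like ratios of 1.28 (vaccine over saline) and 1.51 (combination over saline), and a mitochondrial limit of 8% gave 1.27 and 1.51. At least 500 genes gave a T-like ratio of 0.763 (vaccine over saline) and monocyte-like ratios of 0.569 (vaccine over saline) and 1.41 (combination over vaccine). Immune-named cells as the total gave a phagocyte-like ratio of 1.203 (combination over vaccine). At least 2000 UMIs gave phagocyte-like ratios of 1.204 (combination over vaccine) and 1.66 (combination over saline), and a T-like ratio of 0.479 (combination over saline). The low-UMI sub-cluster counted as T-like gave 0.789, 0.814 and 0.643 in the order of the comparisons. The automatic doublet threshold gave a monocyte-like ratio of 0.941 (vaccine over saline).

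Doublets kept gave a T-like ratio of 0.484 (combination over saline) and monocyte-like ratios of 0.581 (vaccine over saline) and 1.36 (combination over vaccine). Log2 values with doublets kept were 0.57 (vaccine over saline) and 0.26 (combination over saline) for macrophage-like Tigit, 0.58 for macrophage-like Ifng (combination over saline), 0.59 for monocyte-like Gzmb (vaccine over saline), and −0.71 for Gzmb and −0.11 for Ifng in monocyte-like cells (combination over vaccine). List medians were then −0.76 for type I interferon (macrophage-like, combination over vaccine), −0.91 for alternative macrophage (macrophage-like, vaccine over saline), 0.080 for inflammatory (monocyte-like, combination over vaccine), −0.43 and −0.24 for the lipid program (monocyte-like, vaccine and combination over saline), and −0.27 and 0.0023 for chemokines (monocyte-like, vaccine over saline and combination over vaccine). Each cell scaled equally gave −0.61 for type I interferon and −1.17 for alternative macrophage in the same comparisons, 0.082 for mitochondrial transcripts in NK-like cells (vaccine over saline), and stress list medians of −0.049 in regulatory T-like cells (vaccine over saline), −0.021 in macrophage-like and −0.21 in melanoma-like cells (combination over saline). For shares of cells with a UMI, combination over saline ratios were 0.979 for CD8 T-like Cd8a and 0.951 for T-like Ifng without thinning, and 1.01 for CD8 T-like Tigit thinned to 500 UMIs.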

Other observations

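No explanation was tested in this part; all its values belong to classes or genes chosen only after the data were seen, with genes taken from the rule for named genes and the members of the gene lists, and T cell receptor segments looked at apart from that rule. NK-like cells, 109, 145 and 140 in saline, vaccine and combination, differed in their granzymes. Gzmc, an NK and T cell granzyme, was at 347 CPM with saline, 1407 CPM with the vaccine and 1785 CPM with the combination, whereas Gzmg had 174 UMIs with saline and 0 with the vaccine and the combination, and Gzmd 159 UMIs with saline, 0 with the vaccine and 18 with the combination, where a count of 0 allows up to 3. The number of cells that held these granzyme UMIs is not given, so the bound covers the counting of UMIs only. Ccl1, a chemokine of activated lymphocytes, was at 260 CPM [223–302] with the vaccine, 21.1 CPM [9.64–40.0] with saline and 21.6 CPM with the combination. Csf2, which encodes GM-CSF, was at 142 CPM with the vaccine and 25.6 CPM with the combination. Tnfaip3 was at 832 CPM and 920.1 CPM with the vaccine and the combination, against 199 CPM with saline.

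Dendritic-like cells of the type 2 subset had Retnla at 1359.6 CPM with saline, 151 CPM with the vaccine and 21.96 CPM with the combination, and Ccl17 at 356 CPM with saline and 45.0 CPM with the vaccine. In migratory dendritic-like cells Ptgs2, the inducible cyclooxygenase, was at 244 CPM with the vaccine and 20.6 CPM with saline, and Aldh1a2, which makes retinoic acid, at 15.3 CPM and 81.8 CPM. Neutrophil-like cells had the interferon-induced GTPase Gbp4 at 229.8 CPM with the vaccine and 18.3 CPM with saline. Arg1, arginase, was there at 190.2 CPM with the combination and 18.6 CPM with the vaccine. Free macrophage RNA, with all C1q RNA taken as foreign, would give 74.1 CPM and 33.05 CPM. The vaccine level was thus not above this estimate. The scaling shifts in this class are given with the methods.

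Among T cell receptor beta variable segments, Trbv12-2 took 40.9% of the Trbv UMIs of CD8 T-like cells with saline, 36.9% with the vaccine and 30.1% with the combination, of 16504, 9625 and 5524 UMIs. Trbv3 took 16.6%, 16.5% and 16.6%. The files hold 3′ reads, so clones were not resolved.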
